A study of Arabidopsis thaliana with 8 samples.

How the data were processed

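Transcript levels were measured in 12-day-old whole seedlings of Arabidopsis thaliana (ecotype Col-0) of 4 genotypes: wild type, as1-1, tfl2-1 and the as1-1 tfl2-1 double mutant. Each genotype has 2 arrays, 8 in all. Per the labels' protocols, plants grew on MS medium at 22 °C with 16 h of light and 8 h of dark per day at about 100 µE m-2 s-1, and total RNA was amplified and labelled with Cy3 for one-colour hybridisation. The labels call the arrays replicates without saying whether they come from separate cultures. The p-values therefore measure the spread between these samples, which can be partly or wholly technical.

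The deposited scanner files hold 1 intensity per spot. Per the file headers, the processed signal is the spot intensity after background subtraction and detrending by Agilent Feature Extraction, and the submitters' processing notes name version 10.7 of that program. It is on a linear scale and not scaled between arrays. The median intensity of each spot and of its local background are deposited beside it. The authors also deposited a table of values per probe whose making no header or label records. Those values run in parallel with the log2 of the processed signal (r across probes from 0.999 to 1.000 per array), and the medians of the 8 columns are 7.6812, 7.6809 or 7.6817, so the columns had been brought to a common distribution on a log2 scale. That table was used only as an alternative.

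The analysis started from the processed signal. Control spots were left out, as were the 67 spots that Feature Extraction marked as non-uniform or population outliers (4 to 13 per array). Spots of the same probe were averaged. The log2 signal of each array was set to 0 at the 75th percentile of its 43603 non-control probes. A probe was kept when it was well above background, by the program's own flag, on both arrays of at least 1 genotype, which held for 30467 probes (69.9%). Probes were named through the sequence accession that the files give them, matched without its version to the RefSeq gene table of assembly TAIR10.1. Of the probes, 34285 (78.6%) matched a locus and 9318 did not; the latter stand under the name in the files. The files' header names an older genome build than that table, so no coordinates are given. Each gene is represented by its kept probe with the highest mean over the 8 arrays, which left 22668 genes, 19000 of them with a RefSeq locus; 5992 genes had more than 1 kept probe.

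Signal over background limits what can be measured. Between 67.1% and 72.5% of probes were well above background per array, the median signal lay between 170.1 and 238.9, and no spot was saturated. The number of arrays limits the precision. Where a gene was below background on both arrays of 1 of the groups compared, its fold is given as a lower bound, computed against a floor: on each array of the dim group, the lowest signal there that was well above background, or the gene's own signal where that was higher. No fold is given where both groups were below background.

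All 8 arrays entered 1 linear model with a mean per genotype, fitted with limma 3.58.1 in R 4.3.3 (data.table version 1.17.8), with 4 residual degrees of freedom and 2.06 prior degrees of freedom. Comparisons were as1-1, tfl2-1 and the double mutant each against wild type, the double mutant against each parent mutant, and the interaction, which is the as1-1 effect in tfl2-1 plants minus the as1-1 effect in plants with TFL2. Every adjusted p is limma's moderated test with Benjamini-Hochberg adjustment over the 22668 genes of a comparison, two-sided, with a threshold of 0.05. Differences are log2 with the standard error (SE) of the model. The method was tested on simulated data with 100 genes changed per size: it recovered 87% (as1-1), 87% (tfl2-1) and 83% (double mutant) of changes of 1 on the log2 scale, and 59%, 54% and 50% of changes of 0.5. In that test 7.01%, 4.08% and 2.21% of the calls were false. It changed 200 of 22668 genes and drew noise for each gene and array on its own, with no slide effect. In the data 19.2%, 54.7% and 63.7% of genes were called in these comparisons, so the simulated rates do not carry over to them.

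The 23 gene lists held 302 genes, of which 254 were tested. They were tested with limma's camera at its preset correlation of 0.01 between genes, adjusted over the 23 lists of a comparison. The estimated correlation and fry were run beside it. fry asks whether the genes of a list move, on balance, one way, and does not compare them with other genes. A member "rose" or "fell" when its own adjusted p passed the threshold. The lists, the tests and the rule for the genes that the text names were written before the data were examined. The rule takes AS1, TFL2 and the 4 class I KNOX genes; the 5 largest rises and the 5 largest falls against wild type, and the 3 largest of each in the other comparisons, among genes past the threshold that were well above background on both arrays of the groups compared; and up to 4 members of each list with the smallest adjusted p. Where few members passed, the rule adds 1 other member.

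The array identifiers in the files show 2 slides of 4 arrays. Wild type and as1-1 share a slide, and tfl2-1 and the double mutant share the other. The as1-1 effect with or without TFL2, and the interaction, compare arrays within slides, and a slide term in the model leaves them as they are. Comparisons of tfl2-1 or the double mutant with wild type or as1-1 cross the slides, so the design confounds slide with tfl2-1 in them, and spike-in control probes were compared between the slides.

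Alternatives fixed beforehand were quantile normalization, median scaling, no filter on dim probes, a filter for signal on all 8 arrays, the mean of a gene's probes, outlier spots kept, a variance prior with a trend, the replicate number as a block, a slide block, a fit of only the groups compared, the deposited log2 table, and leaving out each array. The planned normexp background correction (offset 50) needed a mean signal that the files do not hold. It was run on the median signal instead, as an alternative chosen after seeing the files. List tests on the arrays of 1 slide, and a wild-type array of its own for as1-1 and for tfl2-1 in their overlap, were also chosen after seeing the data.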

Results

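The data are 8 one-colour microarrays of whole 12-day-old seedlings, with 2 arrays for each of 4 genotypes: as1-1, tfl2-1, the double mutant of both, and wild type (WT). AS1 (ASYMMETRIC LEAVES1) encodes a MYB transcription factor that represses class I KNOX homeobox genes in leaves. TFL2 (TERMINAL FLOWER 2, also called LHP1) encodes a chromodomain protein of the Polycomb pathway. The series compares the mutants with wild type. Per array, 29244 to 31612 of 43603 probes were well above background, with a median signal of 170.1 to 238.9. Across probes, which are not independent replicates, the arrays of a genotype correlated with r of 0.995, and arrays of different genotypes with r of 0.949 to 0.988.

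The mutated genes were looked at first. AS1 mRNA (AT2G37630) was 1.41-fold lower in as1-1 than in wild type (log2 difference -0.49 ± 0.061, SE, n = 2 per genotype, adjusted p = 0.00394) and 1.24-fold lower in tfl2-1 (-0.32, adjusted p = 0.00629). In the double mutant its difference from wild type was 0.02 (adjusted p = 0.771). TFL2 mRNA (AT5G17690) was 2.12-fold lower in tfl2-1 (-1.08 ± 0.061, adjusted p = 4.34e-05) and 1.66-fold lower in the double mutant (-0.73, adjusted p = 0.000129), and its difference in as1-1 was -0.07 (adjusted p = 0.437). The labels give neither the lesions nor the place of the probes on the transcripts, so the mRNA levels, that of AS1 in the double mutant among them, do not check the genotype labels.

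Class I KNOX genes, homeobox genes that act in the shoot meristem, were higher in all 3 mutants, and highest in the double mutant. KNAT1 (AT4G08150) was 3.85-fold higher in as1-1, 1.96-fold higher in tfl2-1 and 9.98-fold higher in the double mutant, with log2 differences of 1.94, 0.97 and 3.32 (SE 0.056, n = 2 per genotype). KNAT2 (AT1G70510) was 2.17-fold and 3.81-fold higher in as1-1 and tfl2-1, with a log2 difference of 3.46 in the double mutant, and KNAT6 (AT1G23380) was 2.23-fold, 2.64-fold and 6.89-fold higher. STM (AT1G62360) was 2.77-fold higher in tfl2-1 and 4.46-fold higher in the double mutant, and in as1-1 it was 1.21-fold higher (log2 difference 0.28 ± 0.073, adjusted p = 0.0467). All 4 genes rose in each mutant, adjusted over all genes and adjusted over the list alone. As a list they shifted up (camera adjusted p = 1.87e-05 in as1-1, 0.00119 in tfl2-1 and 0.000852 in the double mutant), and with an estimated correlation the adjusted p were 0.0947, 0.0855 and 0.124. The comparisons of tfl2-1 and the double mutant with wild type cross the slides. Photosynthesis genes, used as leaf markers, fell in them (17 and 19 of 20 lower, medians -0.38 and -0.66, or -0.09 and -0.12 with quantile normalization, adjusted p = 0.327 and 0.261 with an estimated correlation). The rise of STM in as1-1 did not pass the threshold in 15 of 20 alternative settings, with adjusted p from 0.0145 to 0.184 over all of them. The other probe of STM gave 0.60 in place of 0.28 on the log2 scale in as1-1. With normexp background correction the as1-1 differences of STM, KNAT2 and KNAT6 were 0.17, 0.73 and 0.75.

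**Figure D1:**
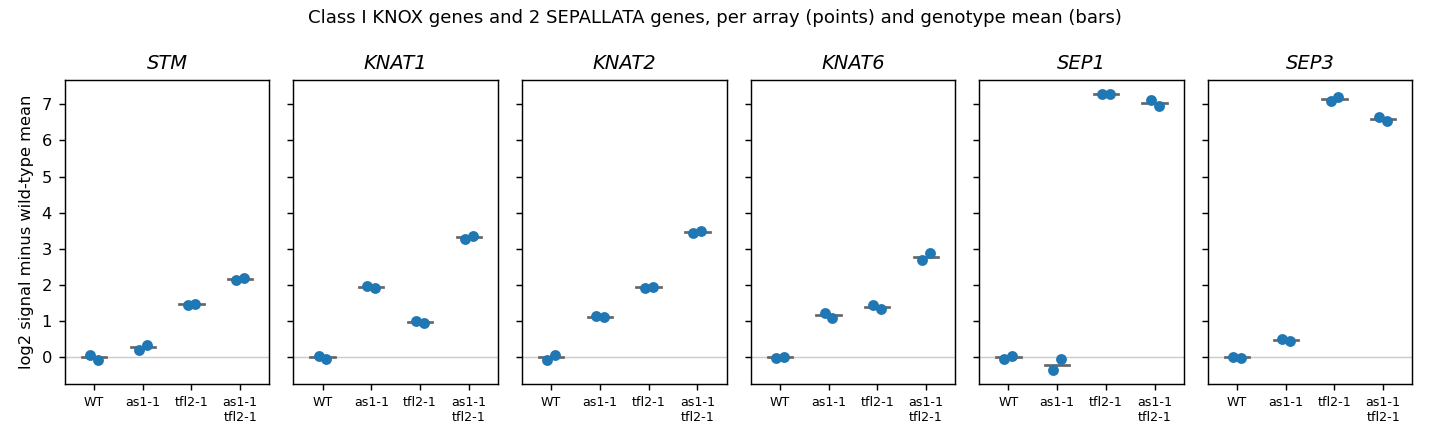
Log2 signal of 4 class I KNOX genes and 2 SEPALLATA genes on each array (points, n = 2 per genotype) and the genotype means (bars), with the wild-type mean of each gene set to 0. KNAT1, KNAT2 and KNAT6 stand above wild type in all 3 mutants and highest in the double mutant (3.32, 3.46 and 2.78), while SEP1 and SEP3 stand between 6.58 and 7.29 above wild type in the genotypes that carry tfl2-1.

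The comparison of as1-1 with wild type asks what the loss of AS1 changes. Of the 5 largest rises, 3 were in genes of AP2-type transcription factors: DDF1 (AT1G12610) was 34.2-fold, CBF2 (AT4G25470) 29.2-fold and CBF1 (AT4G25490) 16.4-fold higher. With normexp background correction CBF2 differed by 3.19 in place of 4.87 on the log2 scale. SRO5 (AT5G62520) was higher by 4.64 on the log2 scale, and AT5G17350 was 21.4-fold higher. The largest falls were in AT5G12340 (7.30-fold lower), the vegetative storage protein genes VSP2 (AT5G24770, 6.12-fold) and VSP1 (AT5G24780, 5.61-fold), AT3G56220 (5.25-fold) and QQS (AT3G30720, 5.12-fold), an orphan gene tied to starch content. SE of these 10 log2 differences lay between 0.050 and 0.153 (n = 2 per genotype), and their adjusted p between 1.27e-06 and 3.89e-05. Beside the largest rises stands a measured shift in genes that respond within minutes to touch, wounding or cold: of 24 such genes, listed after the largest changes were seen and without the largest, 17 rose and 1 fell, with a median log2 difference of 0.95. Of these 24, 5 rose at least 4-fold, and of the other 19, 12 rose and 1 fell, with a median of 0.73. In all, 1607 genes rose and 2746 fell in as1-1, 261 and 256 of them at least 2-fold. The 8 spike-in probes above background differed by -0.185 to -0.091 on the log2 scale, against a median size of 0.402 for called changes. The balance of small rises and falls may therefore depend on the scaling. The total of 4353 was 2667 when only the 4 arrays of that slide were fitted, 2024 without the filter on dim probes, 2423 without WT replicate 1, 2262 without as1-1 replicate 1 and 2392 without as1-1 replicate 2.

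Among developmental lists, leaf polarity genes shifted up in as1-1: 8 of 13 tested rose and 2 fell (9 and 2 adjusted over the list alone, camera adjusted p = 0.0027, 0.116 with an estimated correlation). YAB5 (AT2G26580), a YABBY gene of the abaxial leaf side, was 3.05-fold higher, and AS2 (AT1G65620), whose protein acts together with AS1, was 1.96-fold higher, or 0.37 in place of 0.97 on the log2 scale with normexp background correction. Flowering time genes shifted down, with 6 of 14 lower and 1 higher (7 and 1 adjusted over the list alone, adjusted p = 0.0112, 0.116 with an estimated correlation). The florigen gene FT (AT1G65480) was 2.65-fold (-0.89 in place of -1.41 on the log2 scale with normexp background correction) and AGL24 (AT4G24540) 1.85-fold lower. MAF5 (AT5G65080) differed by -1.31 on the log2 scale, and by -0.60 by its other probe. The list holds both FT and repressors of flowering such as SVP, so its shift gives no direction for flowering. Mitotic cell cycle genes shifted down by small amounts: 9 of 13 fell (10 adjusted over the list alone, median log2 difference -0.20, adjusted p = 0.00306, 0.116 with an estimated correlation). Shoot meristem and organ boundary genes went both ways, 5 of 13 up and 3 down on either adjustment, with a median of 0.38, or 0.01 with dim genes at their bounds, and a mean of -0.05 (adjusted p = 0.122). Among genes above background on all 8 arrays, 9 of its members, the list was called (median 0.41, adjusted p = 0.0349). LOB (AT5G63090), a gene of organ boundaries, was at least 9.57-fold lower in as1-1, where it was below background, by the probe used, and its other probe gave -2.07 on the log2 scale, and normexp background correction -1.44. BOP2 (AT2G41370) was 1.47-fold higher. Of the 16 floral organ identity and floral meristem genes, 3 rose and 1 fell (4 and 1 adjusted over the list alone, adjusted p = 0.173, and 0.0374 over the 6 members above background on all 8 arrays). PI (AT5G20240), a petal and stamen identity gene, was 3.19-fold higher. Of 4 class II KNOX genes 1 fell, and of 8 CIN-type TCP genes 1 fell (1 rose as well adjusted over the list alone); neither list shifted (adjusted p = 0.602 and 0.983).

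Hormone and metabolic lists also moved in as1-1. Of 14 jasmonate and wound genes 13 fell and none rose, on either adjustment (median log2 difference -0.81, camera adjusted p = 2.45e-11). This was the only list of the 23, in any of the 6 comparisons, that passed the threshold with an estimated correlation (adjusted p = 0.0375). Beside VSP1 and VSP2, the repressor gene JAZ10 (AT5G13220) was 3.45-fold and the biosynthetic gene OPR3 (AT2G06050) 2.18-fold lower. Type-A response regulators, which are induced by cytokinin, shifted down: 5 of 9 fell and 1 rose (6 and 1 adjusted over the list alone, adjusted p = 0.0115, 0.116 with an estimated correlation), with ARR15 (AT1G74890) 1.65-fold and ARR6 (AT5G62920) 1.51-fold lower. Among circadian clock genes 8 of 14 fell (11 adjusted over the list alone, adjusted p = 0.00118, 0.116 with an estimated correlation), among them GI (AT1G22770), 1.86-fold lower. Aliphatic glucosinolate genes shifted down, 10 of 17 lower and 2 higher on either adjustment (adjusted p = 0.00752, 0.116 with an estimated correlation); SOT17 (AT1G18590), a sulfotransferase of their synthesis, was 1.84-fold lower. The lists of gibberellin metabolism (4 of 9 up, 2 down), cytokinin metabolism (2 of 8 up, 2 down), auxin biosynthesis (1 of 6 up, 2 down, 3 down adjusted over the list alone), auxin response (4 of 13 up, 1 down), salicylic acid defence (6 of 13 up, 1 down), flavonoid and anthocyanin genes (4 of 12 down) and heat shock genes (2 of 4 down) did not shift (adjusted p between 0.0506 and 0.636). Of these, salicylic acid defence (up, adjusted p = 0.0256) and flavonoid genes (down, 0.03) were called with normexp background correction, and flavonoid genes also among genes above background on all 8 arrays (median -0.39, adjusted p = 0.00666). With fry, which compares no list with other genes, 16 lists were called in as1-1, 19 in tfl2-1 and 20 in the double mutant. Neither did photosynthesis genes (2 of 20 down, 0 adjusted over the list alone, adjusted p = 0.0891), seed maturation genes (3 of 7 down, adjusted p = 0.13), Polycomb complex genes (1 of 16 down, 0 adjusted over the list alone, adjusted p = 0.832) or root markers (1 of 7 down, with 1 up as well adjusted over the list alone, adjusted p = 0.211).

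The comparison of tfl2-1 with wild type asks what the loss of TFL2 changes. Floral genes made the largest rises: SEP1 (AT5G15800) was 156-fold and SEP3 (AT1G24260) 142-fold higher, with log2 differences of 7.29 ± 0.110 and 7.15 ± 0.061 (SE, n = 2 per genotype). The other probe of SEP1 gave 6.15. Both are MADS-box genes that act in every floral organ. All 16 floral organ identity and floral meristem genes rose, on either adjustment (camera adjusted p = 5.09e-10, 0.0658 with an estimated correlation). In wild type 7 of the 16 were below background on both arrays, and with those at their lower bounds the median log2 difference was 4.02. SHP1 (AT3G58780), a carpel gene, was 21.4-fold and PI 12.2-fold higher. Outside that list the largest rises were in AT3G19550 (54.5-fold), the sugar transporter gene SWEET10 (AT5G50790, 51.8-fold) and AT3G28500 (45.9-fold). The largest falls were in XTH31 (AT3G44990, 22.9-fold lower), a cell wall enzyme gene, AT4G22485 (16.5-fold), MSRB6 (AT4G04840, 15.3-fold), IAA29 (AT4G32280, 13.8-fold), an Aux/IAA gene, and GA3OX1 (AT1G15550, 12.5-fold), whose enzyme makes active gibberellin. Of these 10 changes, the adjusted p lay between 2.34e-07 and 9.75e-05. In all, 5942 genes rose and 6449 fell, 969 and 984 of them at least 2-fold. Wild type and tfl2-1 were hybridised on different slides. The 8 spike-in probes above background differed between them by at most 0.212 on the log2 scale. For changes under 2-fold slide and mutation cannot be told apart. For larger changes these probes argue only against a general shift of that size, not against an effect of the slide on single genes. Leaf photosynthesis genes fell along with these changes (median log2 difference -0.38, or -0.09 with quantile normalization).

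Flowering time genes shifted up in tfl2-1, with 11 of 14 higher and 1 lower on either adjustment (adjusted p = 0.000144, 0.0658 with an estimated correlation). FT was 14.7-fold and the shoot identity gene TFL1 (AT5G03840) 8.10-fold higher, AGL17 (AT2G22630) was at least 28.6-fold higher (2.95 on the log2 scale with normexp background correction), and SVP (AT2G22540), a repressor of flowering, was 2.19-fold lower. Shoot meristem and organ boundary genes shifted up (9 of 13 up and 1 down, 11 and 2 adjusted over the list alone, adjusted p = 0.00211, 0.189 with an estimated correlation); RPL (AT5G02030) was 2.57-fold, LOB 2.34-fold and BOP2 1.66-fold higher, and CUC1 (AT3G15170) at least 3.46-fold higher (0.55 on the log2 scale with normexp background correction). That shift was not called among genes above background on all 8 arrays, which left 9 of the list's members. Class II KNOX genes shifted up (3 of 4 on either adjustment, adjusted p = 0.0337, 0.274 with an estimated correlation), with KNAT3 (AT5G25220) 1.66-fold higher. CIN-type TCP genes, which restrain leaf cell division, shifted down (5 of 8 down and 1 up on either adjustment, adjusted p = 0.0337, 0.161 with an estimated correlation), with TCP3 (AT1G53230) 2.31-fold and TCP4 (AT3G15030) 1.62-fold lower. Leaf polarity genes did not shift (4 of 13 up and 1 down on either adjustment, adjusted p = 0.646), and their median of 0.09 and mean of -0.09 differed in sign; YAB5 was 5.03-fold lower. Photosynthesis genes moved along with each of these lists: 17 of 20 fell on either adjustment (median log2 difference -0.38, adjusted p = 8.73e-05, 0.327 with an estimated correlation). With quantile normalization their median was -0.09 and the shift was not called (adjusted p = 0.276, with 8.73e-05 to 0.327 over all alternatives).

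Among hormone lists in tfl2-1, all 9 type-A response regulators fell, on either adjustment (median log2 difference -1.60, adjusted p = 1.27e-05, 0.0658 with an estimated correlation). ARR15 was 10.4-fold, ARR6 8.65-fold and ARR7 (AT1G19050) 5.99-fold lower. Cytokinin metabolism genes went both ways (3 of 8 up and 3 down on either adjustment, adjusted p = 0.984, median -0.44 and mean 0.54). The cytokinin oxidase gene CKX3 (AT5G56970) was at least 49.1-fold higher (3.68 on the log2 scale with normexp background correction), and CKX4 (AT4G29740) 6.85-fold lower. Auxin response genes shifted down, 10 of 13 lower (10, and 1 higher, adjusted over the list alone, adjusted p = 0.000144, 0.0658 with an estimated correlation), with IAA1 (AT4G14560) 5.57-fold and IAA19 (AT3G15540) 4.21-fold lower. Auxin biosynthesis genes shifted down, 4 of 6 on either adjustment (adjusted p = 0.019, 0.156 with an estimated correlation), with YUC2 (AT4G13260) 3.97-fold and TAA1 (AT1G70560) 2.70-fold lower. Gibberellin metabolism genes did not shift as a list (2 of 9 up and 6 down on either adjustment, adjusted p = 0.0745). They were called with normexp background correction (adjusted p = 0.0211). Salicylic acid defence genes shifted down, 9 of 13 on either adjustment (adjusted p = 0.00204, 0.0855 with an estimated correlation), with EDS5 (AT4G39030) 2.87-fold and PAD4 (AT3G52430) 1.94-fold lower (-0.96 on the log2 scale, and -2.36 and -0.90 by its other probes). Jasmonate and wound genes went both ways, 4 of 14 up and 8 down on either adjustment (adjusted p = 0.116). VSP1 was 7.51-fold (a log2 difference of 2.91, and 3.59 to 4.17 by its other probes) and VSP2 6.63-fold higher, and AOC1 (AT3G25760) 3.95-fold and AOS (AT5G42650) 3.76-fold lower, the latter pair being biosynthetic genes. Clock genes shifted down, 9 of 14 lower and 1 higher on either adjustment (adjusted p = 0.0174, 0.156 with an estimated correlation), GI being 5.94-fold lower and RVE1 (AT5G17300) 2.86-fold higher. Aliphatic glucosinolate genes shifted up, 11 of 17 higher and 3 lower on either adjustment (adjusted p = 0.0182, 0.156 with an estimated correlation), with BCAT4 (AT3G19710) 2.06-fold higher. The lists of mitotic cell cycle genes (3 of 13 up, 1 down), Polycomb complex genes (4 of 16 up, 3 down, 2 and 3 adjusted over the list alone), seed maturation genes (2 of 7 up, 2 down, 3 and 2 adjusted over the list alone), flavonoid and anthocyanin genes (2 of 12 up, 5 down), root markers (2 of 7 down) and heat shock genes (0 of 4) did not shift (adjusted p between 0.408 and 0.984). EMF1 (AT5G11530), a Polycomb partner gene, was 1.89-fold higher. These comparisons cross the slides as well.

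**Figure D2:**
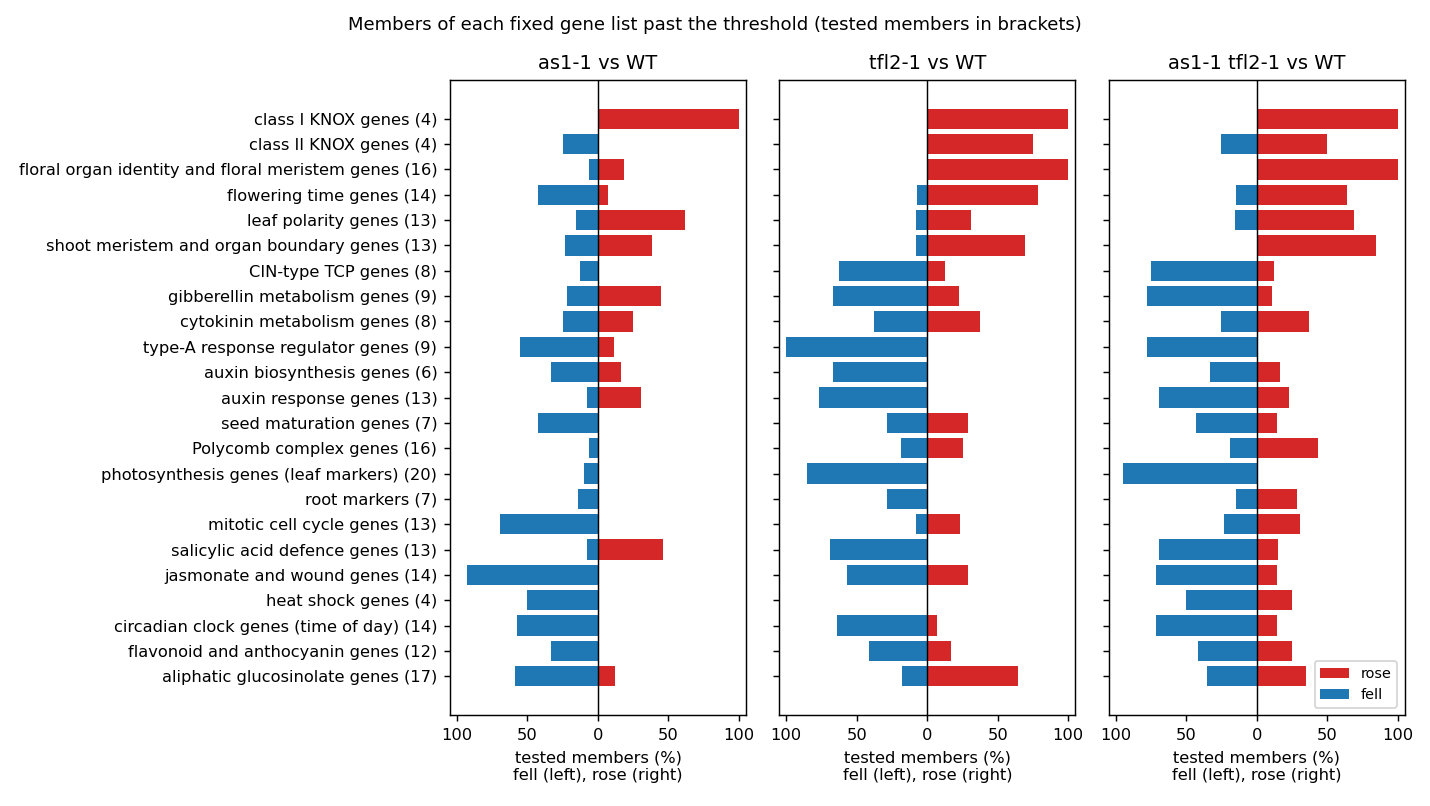
Share of the tested members of each of the 23 gene lists that rose (red, right) or fell (blue, left) past the threshold in each mutant against wild type, in percent, with the number tested in brackets. All 16 floral genes rose in tfl2-1 and in the double mutant, and 13 of 14 jasmonate and wound genes fell in as1-1; the tfl2-1 and double mutant panels cross the slides.

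The comparison of the double mutant with wild type asks what the loss of both genes changes. SEP1 was 131-fold, SEP3 95.9-fold, SWEET10 60.5-fold, AT3G28500 53.7-fold and SHP1 37.6-fold higher. The other probe of SEP1 gave 5.98 in place of 7.04 on the log2 scale. The largest fall was in MSRB6, 176-fold lower (log2 difference -7.46 ± 0.091, SE, n = 2 per genotype), followed by the glucosinolate synthesis gene IMS2 (AT5G23020, 23.8-fold), AT1G66100 (23.6-fold), CYP81F2 (AT5G57220, log2 difference -4.12), a gene of indole glucosinolate modification, and XTH31 (15.5-fold). All 16 floral genes rose on either adjustment (adjusted p = 1.03e-08, 0.124 with an estimated correlation), and with the 7 that were below background in wild type at their bounds the median log2 difference was 4.43. Shoot meristem and organ boundary genes shifted up, 11 of 13 on either adjustment (adjusted p = 6.66e-05, 0.124 with an estimated correlation); CUC3 (AT1G76420) was 4.87-fold higher, BOP2 was higher by 2.04 on the log2 scale, and CUC1 was at least 5.79-fold higher. With normexp background correction CUC3 differed by 1.35 in place of 2.29 on the log2 scale, and CUC1 by 0.94. Flowering time genes shifted up, 9 of 14 higher and 2 lower on either adjustment (adjusted p = 0.00934, 0.124 with an estimated correlation), with FT 4.78-fold and CO (AT5G15840) 2.17-fold higher. Leaf polarity genes shifted up (9 of 13 up and 2 down on either adjustment, adjusted p = 0.047, 0.227 with an estimated correlation), with AS2 2.86-fold higher (0.74 in place of 1.52 on the log2 scale with normexp background correction) and YAB5 1.78-fold lower; that call was lost with quantile normalization. In all, 6982 genes rose and 7455 fell, 1202 and 1592 of them at least 2-fold. Photosynthesis genes fell along with these lists, 19 of 20 (20 adjusted over the list alone, median -0.66, adjusted p = 2.55e-06, 0.261 with an estimated correlation), LHCB2.1 (AT2G05100) being 6.24-fold and LHCB3 (AT5G54270) 2.82-fold lower; with quantile normalization their median was -0.12. The double mutant and wild type lie on different slides, with differences of at most 0.322 on the log2 scale in those 8 spike-in probes, and the limits given for tfl2-1 hold here too.

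Hormone and metabolic lists in the double mutant moved mostly down. Type-A response regulators fell, 7 of 9 on either adjustment (adjusted p = 0.00483, 0.124 with an estimated correlation), with ARR15 4.32-fold and ARR6 3.23-fold lower. Auxin response genes shifted down, 9 of 13 lower and 3 higher on either adjustment (adjusted p = 0.00753, 0.124 with an estimated correlation), with IAA19 12.1-fold lower and IAA2 (AT3G23030) at a log2 difference of -2.04. Gibberellin metabolism genes shifted down, 7 of 9 lower and 1 higher (8 and 1 adjusted over the list alone, adjusted p = 0.0267, 0.26 with an estimated correlation), with GA3OX1 7.14-fold and GA2OX6 (AT1G02400) 2.68-fold lower. The shifts of the auxin response and gibberellin lists were not called among genes above background on all 8 arrays. Jasmonate and wound genes shifted down, 10 of 14 lower and 2 higher on either adjustment (adjusted p = 0.0077, 0.124 with an estimated correlation), with AOC1 6.90-fold lower and VSP1 5.48-fold higher (2.46 on the log2 scale, and 3.16 to 3.83 by its other probes). Clock genes shifted down, 10 of 14 lower and 2 higher on either adjustment (adjusted p = 0.00778, 0.124 with an estimated correlation), with GI 10.9-fold lower. Salicylic acid defence genes shifted down, 9 of 13 lower and 2 higher on either adjustment (adjusted p = 0.036, 0.167 with an estimated correlation), with EDS5 3.33-fold lower. The lists of class II KNOX genes (2 of 4 up, 1 down), CIN-type TCP genes (1 of 8 up, 6 down), cytokinin metabolism (3 of 8 up, 2 down), auxin biosynthesis (1 of 6 up, 2 down), aliphatic glucosinolate genes (6 of 17 up, 6 down), flavonoid and anthocyanin genes (3 of 12 up, 5 down), mitotic cell cycle genes (4 of 13 up, 3 down), Polycomb complex genes (7 of 16 up, 3 down), seed maturation genes (1 of 7 up, 3 down) and heat shock genes (1 of 4 up, 2 down) did not shift (adjusted p between 0.0822 and 0.848). Root markers did not shift either (2 of 7 up, 1 down, adjusted p = 0.747), and for SCR (AT3G54220) the probes disagreed, with log2 differences of 0.38 and -0.75.

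Against as1-1, the double mutant shows the effect of tfl2-1 in plants that carry as1-1, and again crosses the slides. SEP1 was 151-fold (7.24 on the log2 scale, and 6.36 by its other probe), AT3G28500 109-fold and AT3G19550 80.5-fold higher, and MSRB6 113-fold, SRO5 65.7-fold and AT2G17660 61.2-fold lower. Here 7368 genes rose and 6565 fell, and 11 lists shifted (0 with an estimated correlation), led by the floral genes (all 16 up on either adjustment, camera adjusted p = 3.35e-08, 0.124 with an estimated correlation), with a median of 4.41. Photosynthesis genes fell beside them, 18 of 20 on either adjustment (median -0.58, adjusted p = 1.82e-06, 0.276 with an estimated correlation; median -0.14 with quantile normalization). The rapidly induced genes named above were lower in the double mutant, all 24 of them (median -1.61).

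Against tfl2-1, on the same slide, the double mutant shows the effect of as1-1 in plants that carry tfl2-1. The largest rises were in AT1G49570 (14.5-fold), AT3G05727 (9.05-fold) and AT4G22485 (7.81-fold), and the largest falls in IMS2 (13.1-fold), MSRB6 (11.5-fold) and EXLB1 (AT4G17030, 9.59-fold), an expansin-like gene. Class I KNOX genes rose again, all 4 on either adjustment (camera adjusted p = 4.4e-05, 0.0812 with an estimated correlation), KNAT1 being 5.08-fold, KNAT2 2.88-fold, KNAT6 2.61-fold and STM 1.61-fold higher. Shoot meristem and organ boundary genes shifted up, 11 of 13 up and 1 down (12 and 1 adjusted over the list alone, adjusted p = 1.09e-05, 0.123 with an estimated correlation). Aliphatic glucosinolate genes fell, 10 of 17 (11 adjusted over the list alone, adjusted p = 7.89e-05, 0.0823 with an estimated correlation), as did jasmonate and wound genes, 12 of 14 with 2 higher on either adjustment (adjusted p = 1.31e-05, 0.0812 with an estimated correlation). Photosynthesis genes fell beside them, 11 of 20 on either adjustment (median -0.30, adjusted p = 1.09e-05, 0.409 with an estimated correlation; median -0.11 with quantile normalization). In all 3059 genes rose and 4086 fell; the total of 7145 was 4359 without the filter on dim probes and 4399 to 4713 when an array of tfl2-1 or of the double mutant was left out. MSRB6 differed by -2.23 in place of -3.52 on the log2 scale with normexp background correction.

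The interaction asks whether the as1-1 effect differs between plants with and without TFL2, and it was tested within slides. Of the genes, 2405 had a higher and 2192 a lower as1-1 effect in tfl2-1 plants, 332 and 460 of them by at least 2-fold. The lowest interactions on the log2 scale were -5.27 ± 0.129 for SRO5 (SE, n = 2 per genotype), -4.95 for CBF1 and -4.45 for AT5G17350. Of the 24 rapidly induced genes, 18 had a lower and 1 a higher as1-1 effect in tfl2-1 plants (median -1.48, camera adjusted p = 3.06e-16, 0.00976 with an estimated correlation). The highest interactions were 3.26 for AT4G12490, 2.88 for MRD1 (AT1G53480) and 2.85 for AT4G33560. For KNAT1, KNAT2 and STM the interaction was 0.40, 0.41 and 0.41 (adjusted p = 0.0197, 0.02 and 0.0395), and for KNAT6 it was 0.23 (adjusted p = 0.236). With normexp background correction KNAT2 gave 0.65, and KNAT6 0.47 with a call (adjusted p = 0.0158). The other probes of STM and KNAT1 gave 0.07 and 0.12 (adjusted p = 0.779 and 0.478), and the class I KNOX list was not called (3 of 4 up on either adjustment, camera adjusted p = 0.0542, 0.31 with an estimated correlation). It was called with normexp background correction, among genes above background on all 8 arrays and with fry (adjusted p = 0.00886, 0.0427 and 0.00331). The calls of KNAT1, KNAT2 and STM were lost in 6, 6 and 10 of 19 alternative settings, and with the mean of a gene's probes KNAT1 and STM gave 0.26 and 0.24. Type-A response regulators had higher as1-1 effects without TFL2, 8 of 9 on either adjustment (camera adjusted p = 4.12e-06, 0.129 with an estimated correlation). The total of 4597 was 1978 without the filter on dim probes, 2821 and 3019 without as1-1 replicate 1 or 2, 3037 and 2719 without tfl2-1 replicate 1 or 2, and 2983 and 3039 without replicate 1 or 2 of the double mutant.

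**Figure D3:**
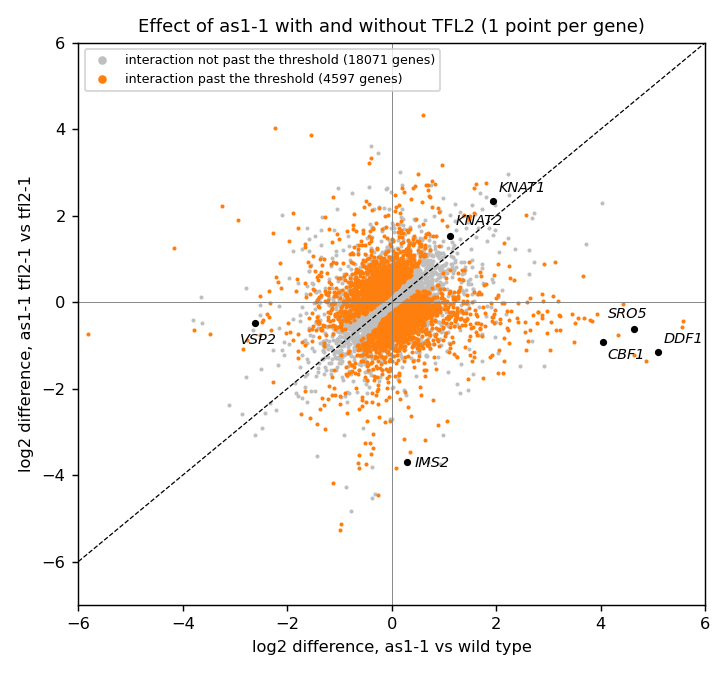
Log2 difference between as1-1 and wild type (horizontal) against that between the double mutant and tfl2-1 (vertical), 1 point per gene, n = 2 arrays per genotype, with orange for the 4597 genes whose interaction passed the threshold and a dashed line where both effects are equal. KNAT1 and KNAT2 lie near the line, while SRO5, CBF1 and DDF1, which rose in as1-1, lie below 0 on the vertical axis.

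Overlaps between comparisons were counted over the 22668 genes. As1-1 and tfl2-1 shared 669 genes that rose and 1421 that fell, against 421 and 781 for independent lists of those sizes. In opposite directions, 523 rose in as1-1 and fell in tfl2-1 and 646 did the reverse, against 457 and 720. Across genes, which are not independent replicates, the log2 differences correlated with r of 0.08 and rho of 0.24. Both comparisons use the same wild-type arrays: 100 simulations of unchanged groups gave an r of 0.50 and 0.01 shared calls per direction, and a covariance of 0.0134 against 0.0235 observed, a difference of 0.0101. With a wild-type array of its own for each comparison, an alternative chosen after seeing the data, the covariance was 0.0083 or 0.0014, with 476 or 340 shared genes up (287 or 207 for independent lists) and 803 or 639 down (437 or 369). The covariance was thus lower with separate wild-type arrays, and part of it may come from the shared controls. The shared calls still exceeded those of independent lists, in fits with a lone wild-type array per comparison. The simulated groups hold no changed genes, so their 0.01 shared calls are no reference for the observed overlap. The as1-1 effect with and without TFL2, which share no array, had 484 genes up and 1148 down in both (217 and 495 for independent lists, r = 0.16, rho = 0.19). Another 350 rose with TFL2 and fell without it, and 355 did the reverse (290 and 371 for independent lists). The tfl2-1 effect with and without as1-1 had 4675 up and 4790 down in both (1931 and 1868 for independent lists, r = 0.76, rho = 0.75), and both of those comparisons cross the slides. The shared calls of as1-1 and tfl2-1 were 263 and 559 without the filter on dim probes, and 335 to 365 and 638 to 715 without WT replicate 1 or an as1-1 array.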

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

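Tests chosen only after the results were seen are those on the double mutant against tfl2-1 for the genes raised in as1-1, on the rapidly induced genes that were not themselves raised 4-fold, on jasmonate and wound genes in as1-1, on the largest spike-in difference, and on dawn-phased and evening-phased genes. The full list of rapidly induced genes was also drawn up after the largest changes were seen, though its prediction was written before its test.

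The as1-1 effect differed between plants with and without TFL2, by a test of the difference itself, for 4597 genes. Among the genes named by rule these were AS1 (interaction on the log2 scale 0.83), TFL2 (0.43), STM (0.41), KNAT1 (0.40) and KNAT2 (0.41), of which the calls of TFL2, STM, KNAT1 and KNAT2 were lost in 7, 10, 6 and 6 of 19 alternative settings and other probes of STM and KNAT1 gave 0.07 and 0.12 without a call, AT4G12490 (3.26), MRD1 (2.88) and AT4G33560 (2.85), and, in the other direction, SRO5 (-5.27), CBF1 (-4.95) and AT5G17350 (-4.45). Of the gene lists, 5 differed: shoot meristem and organ boundary genes (median 0.65, or 0.56 over the 9 members above background in every genotype), type-A response regulator genes (0.69, or 0.82 over 8 such members), photosynthesis genes (-0.22), mitotic cell cycle genes (0.27) and jasmonate and wound genes (0.53). With an estimated correlation none of the 5 passed the threshold (adjusted p between 0.129 and 0.583). The rapidly induced genes weighed below moved with SRO5 and CBF1: 18 of 24 had a lower as1-1 effect in tfl2-1 plants (median -1.48, adjusted p = 3.06e-16, 0.00976 with an estimated correlation).

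In as1-1, 78 genes rose at least 4-fold over wild type, with DDF1, CBF2 and SRO5 at their head. If handling or harvest of the as1-1 seedlings were the cause, genes induced within minutes by touch, wounding or cold would be higher too, and 17 of 24 rose, with a median log2 difference of 0.95 (camera adjusted p = 7.39e-17, 0.00907 with an estimated correlation). Since 5 of the 24 are among the 78, that value partly repeats the pattern, and the test rests on the other 19: 12 rose and 1 fell, with a median of 0.73 (camera p = 5.71e-11, 0.00374 with an estimated correlation), TCH4 being higher by 1.65 and CML39 lower by 1.39. The 24 were lower in tfl2-1 and the double mutant than in wild type (medians -0.43 and -0.94, 15 and 17 fell, adjusted p = 0.00882 and 0.000194, 0.158 and 0.0583 with an estimated correlation) and in the double mutant than in tfl2-1 (-0.30, 13 fell, adjusted p = 1.08e-05, 0.037 with an estimated correlation), so they differ between other groups too. A loss of AS1 that acts in the same way with and without TFL2 is argued against for the 78 genes as a set, though not for each of them. Their median log2 difference between the double mutant and tfl2-1 was -0.36, with 27 called lower and 12 called higher. The interaction was called lower for 71 and higher for 0. It subtracts the as1-1 rises by which the 78 genes were picked, so its direction was nearly fixed and adds no support. Wounding early enough to act through jasmonate would raise jasmonate and wound genes. Of these, 13 of 14 fell in as1-1 and none rose (median -0.81, camera adjusted p = 2.45e-11, 0.0375 with an estimated correlation). The list also fell in the double mutant against tfl2-1 (median -0.63), so a lowering that goes with as1-1 could hide such a rise. The test, chosen after these values were seen, therefore does not decide on wounding. Handling, such as touch, cold or wounding at harvest, may explain the rises of the 78 genes. The rapidly induced genes were listed after the largest rises were seen, and an as1-1 effect on such genes would raise them too. Their rise, also that of the 19, therefore does not tell handling from genotype. An as1-1 effect that needs TFL2 stays open as untested, because genotype and handling are confounded in 1 group of 2 arrays.

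The comparisons of tfl2-1 with wild type cross the slides. Of 10 spike-in probes, 8 were above background, and between tfl2-1 and wild type their median absolute log2 difference was 0.114, against 0.442 for the median size of a called tfl2-1 change, and 0.124 and 0.150 within the slides (as1-1 against wild type, the double mutant against tfl2-1). The spike-in difference was not small enough beside the called size to meet the bound set for excluding the slide, so for small changes a difference in hybridisation or scanning between the slides and the mutation cannot be told apart. Between tfl2-1 and wild type the largest absolute difference among the 8 spike-in probes was 0.212. It argues against a general shift of 2-fold or more between the slides. All 8 differed downwards there (-0.212 to -0.063), and also within the slides. The ranges were -0.185 to -0.091 in as1-1 against wild type and -0.221 to -0.098 in the double mutant against tfl2-1. An offset between spike-in probes and scaled signal is thus present within slides too, and limits small changes there. These 8 control probes cannot show an effect of the slide on single genes, so for those larger changes are not resolved either. The labels give the same age, temperature and light for all 8 samples and name no growth or harvest batch, so none was tested, and the mutation stays open.

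Clock genes shifted down against wild type at the preset correlation (as1-1 8 of 14 lower, tfl2-1 9 lower and 1 higher, the double mutant 10 lower and 2 higher), but not with an estimated correlation (adjusted p = 0.116, 0.156 and 0.124). A shift of a few hours in harvest time may move dawn-phased and evening-phased genes in opposite directions: in the double mutant the dawn-phased median was 0.256 (4 rose and 4 fell, from -3.71 to 2.14, adjusted p = 0.917, 0.928 with an estimated correlation) and the evening-phased median -0.807 (8 of 10 fell, adjusted p = 0.00143, 0.0583 with an estimated correlation). In as1-1 the medians were -0.470 (2 of 11 rose and 5 fell, adjusted p = 0.0883, 0.189 with an estimated correlation) and -0.292 (5 of 10 fell, adjusted p = 0.0053, 0.0573 with an estimated correlation), the same sign, which argues against such a shift there without excluding it, and in tfl2-1 0.270 and -0.322. The condition on both adjusted p was added after these values were seen. With dawn-phased genes going both ways in each mutant, harvest time and an effect of the mutations on the clock cannot be told apart.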

How the results depend on the processing

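Normexp on the median signal, list tests on the arrays of 1 slide, and a wild-type array of its own for each comparison were chosen after seeing the data; the other alternatives were planned. Normexp on the mean signal was not run, as the files lack that column.

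Without the filter on dim probes more genes were tested, and the counts were 2024 for as1-1 against wild type, 4359 for the double mutant against tfl2-1 and 1978 for the interaction. Shared calls of as1-1 and tfl2-1 were then 263 up and 559 down, and those of the as1-1 effect with and without TFL2 219 and 537. With only the groups compared in the fit, which uses fewer arrays, 2667 genes changed in as1-1, with overlaps of 347 and 789, and of 291 and 687. With a wild-type array of its own for as1-1 (replicate 1 or 2) and for tfl2-1, the shared calls were 476 or 340 up and 803 or 639 down. Over all alternatives except leaving out an array, the tfl2-1 count ran from 9936 to 12929 and the double mutant count from 12716 to 14877. With the replicate number as a block the as1-1 count was 3454, and leaf polarity and salicylic acid defence in the double mutant were not called, while salicylic acid defence in as1-1 was (adjusted p = 0.0494); deviations of arrays with the same number correlated between genotypes with r from -0.049 to 0.055, so the numbers pair nothing.

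Leaving out 1 array at a time leaves a lone array that is assumed to vary like the other groups. The counts then ran from 2262 to 3641 for as1-1, 4399 to 6959 for the double mutant against tfl2-1 and 2719 to 3872 for the interaction. Overlaps of as1-1 and tfl2-1 ran from 335 to 613 up and 638 to 1161 down, and of the as1-1 effect with and without TFL2 from 291 to 394 and 659 to 834. Of the 12 rises of class I KNOX genes against wild type, 11 passed the threshold without any 1 array; the exception was STM in as1-1.

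List shifts depend on the correlation assumed between genes. With an estimated correlation 1 list passed in as1-1 (8 at the preset) and 0, 0, 0, 0 and 0 in tfl2-1, the double mutant, the double mutant against as1-1, the double mutant against tfl2-1 and the interaction (13, 12, 11, 8 and 5). With fry, which compares no list with other genes, the numbers were 16 in as1-1, 20 in the double mutant, 17 and 16 in the double mutant against as1-1 and tfl2-1, and 16 in the interaction.

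Of 6019 values of named genes under alternatives, 5757 kept direction and side of the threshold, 257 no longer passed, 3 newly passed and 2 reversed. The 112 values of the slide block could not differ, since that term leaves the fit as it is. Leaving out an array outside a comparison also keeps its log2 difference, so those values could not reverse. SESA3 (AT4G27160) in tfl2-1 was 0.95 in place of -3.72 without the filter, and SCR (AT3G54220) in the double mutant -0.19 in place of 0.38 with the mean of its probes, whose log2 differences were 0.38 and -0.75. For SESA3 that setting changes only which probe stands for the gene, so the value without the filter comes from a probe that the filter leaves out. Of 868 list values 740 kept both, 65 no longer passed, 63 newly passed and 0 reversed. Signal over background limits the folds of dim genes, which normexp with its offset of 50 makes smaller: CBF2 in as1-1 was 3.19 in place of 4.87.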

Other observations

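The families below were tested only after the data had been seen. Genes were grouped by the letters of their symbol, and 55 families of at least 15 tested genes were tested with camera, adjusted over the families of a comparison. SPL genes, squamosa-promoter-binding-like transcription factors, were higher in tfl2-1 (8 of 15 rose and 1 fell, adjusted p = 0.0257) and in the double mutant (10 of 15 rose and 2 fell, adjusted p = 0.0108), with adjusted p = 0.376 and 0.375 with an estimated correlation. SPL3 was higher by 1.97 and 2.73 and SPL4 by 2.04 and 2.69 on the log2 scale. AGP genes, which encode arabinogalactan proteins, were higher in as1-1 (9 of 26 rose and 2 fell, adjusted p = 0.00702, 0.446 with an estimated correlation), and their as1-1 effect was lower without TFL2 (15 of 26, with 1 higher, adjusted p = 5.8e-07, 0.336 with an estimated correlation). Genes named RPL with a number, a name used for proteins of the large ribosomal subunit, were lower in tfl2-1 (15 of 21 fell, adjusted p = 0.0147, 0.376 with an estimated correlation). REPLUMLESS, whose symbol RPL has no number, is not among them. Comparisons with tfl2-1 arrays against wild type cross the slides, and photosynthesis genes fell in tfl2-1 and the double mutant too (17 and 19 of 20, medians -0.38 and -0.66, or -0.09 and -0.12 with quantile normalization, adjusted p = 0.327 and 0.261 with an estimated correlation).

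The root markers show which of the listed genes gave signal in the whole seedlings. Of 21 listed genes, all on the array, 4 were well above background on all 8 arrays and 9 on none. Those on none were PLT1, PLT2, EXPA7, RHD6, IRT1, LRX1, PRP3, CASP5 and SMB. The tests of this list rest on 7 genes, so they say little about roots.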
